A study of Homo sapiens with 10 samples.

How the data were processed

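Gene expression was measured on 10 Affymetrix Clariom S arrays of HT29 cells: 4 from decellularized colorectal cancer liver metastasis matrix (CRLM), 4 from decellularized healthy liver matrix (HL) and 2 from flat culture on plastic. The deposited values are log2 expression per probe set, normalized by the authors with RMA per the submitters' processing notes. The software and version used for RMA are not given in the sources used here. The table holds 20889 probe sets with values from 1.92 to 13.4 and no missing value, and no detection calls were used. The number of arrays limits the precision.

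Groups and donor numbers were taken from the labels. Each of 4 donors has 1 CRLM and 1 HL array, so the donor numbers of the labels pair these arrays. The deviations of both arrays of a donor from their group means correlated across genes at 0.65, -0.56, -0.22 and 0.12 for donors 1 to 4. Gene names came from the platform's probe table, with symbols checked against RefSeq genes. Of 17702 probe sets with 1 symbol, 22 for Y-linked genes and XIST were left out, which left 17680 probe sets of 17662 genes. The 3187 probe sets without a symbol were left out of these tests. Of several probe sets of a gene, the one with the highest mean was named.

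R 4.3.3 with limma 3.58.1 was used for all tests. A mean per group was fitted to all 10 arrays with lmFit, the spread was moderated with eBayes at default settings, and two-sided p-values were adjusted with Benjamini-Hochberg over all 17680 probe sets in each comparison (threshold 0.05). The comparisons were CRLM against HL, CRLM against plastic, HL against plastic, and both matrices against plastic. Errors of log2 changes are standard errors of this fit. Gene lists (36 lists of 915 genes, 803 of them measured) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with p-values adjusted over the lists of a comparison, and members past the threshold were counted over all genes and adjusted over the list alone. Lists needed at least 5 measured genes. Mean list scores of CRLM and HL arrays were compared by two-sided exact permutation. Calls in both matrices were compared with 100 simulated draws of unchanged groups against shared controls.

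Genes named in each comparison were the 10 with the largest rise and the 10 with the largest fall among those past the threshold with the same sign on every array (against both plastic arrays) or in every donor pair. Where none passed, the 5 with the smallest p in each direction were taken and are said not to have passed. Of each list, up to 4 genes with the smallest p were named. Groups, tests, lists and this rule were fixed before the data were examined.

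Alternatives were quantile normalization, centring of arrays on their medians, a filter that kept probe sets above 6.88 on at least 2 arrays, eBayes with trend and robust, array weights, donor as a random or fixed block, a fit of the 8 matrix arrays alone, at least 2-fold change, a threshold of 0.01 and each array left out in turn. After the data had been seen, the SD of the array as a covariate and a fit without CRLM 2, HL 3 and HL 4 were added. That fit keeps only HL 1 and HL 2 in the HL group, and CRLM 1, CRLM 3 and CRLM 4 in the CRLM group. The pipeline was tested on simulated data of 17680 genes with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 93% of 2-fold changes in CRLM against HL, 80% in CRLM against plastic and 76% in HL against plastic. It recovered 100% of 4-fold changes in each, with 5, 13 and 16 false calls. These values hold for the simulated data. Of 35 splits of the real matrix arrays into equal groups, 3 called genes, up to 5634. Recovery and false calls on the real arrays may therefore differ from the simulated values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.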

Results

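Expression was measured on 10 Affymetrix Clariom S arrays in HT29, an established human colon adenocarcinoma line that here carried ZsGreen and luciferase reporters. The cells had been grown in decellularized matrix of colorectal cancer liver metastases (CRLM, n = 4 arrays), in decellularized matrix of healthy liver (HL, n = 4 arrays) or flat on plastic (n = 2 arrays). The labels number 4 tissue donors, each of whom gave 1 CRLM and 1 HL matrix, and arrays are named here by group and donor number. Cells entered the matrices in collagen I, so matrix cultures differed from plastic in collagen I as well as in tissue matrix. Because 1 cell line was used, p-values measure a spread between matrices and cultures that may in part be technical. The labels speak of 3 independent experiments for RNA extraction beside 4 donors, and do not say whether the 2 plastic arrays come from separate cultures.

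After the authors' normalization, array medians lay between 6.79 and 6.85 on the log2 scale. The SD of all values on an array ran from 1.70 on HL 4 to 1.83 on CRLM 1, with 1.71 on CRLM 2 and 1.73 on HL 3. The first principal component held 40.6% of the variance and spread the matrix arrays from -30.6 (CRLM 1) to 31.8 (HL 4), with both matrix types at either end. The second component held 25.2% and set the plastic arrays (-33.5 and -32.7) apart from the matrix arrays (-2.98 to 16.7). Correlations between arrays were 0.966 to 0.989 within CRLM, 0.957 to 0.989 within HL, 0.989 between the plastic arrays and 0.959 to 0.992 between arrays of different groups. The number of arrays limits the precision.

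**Figure D1:**
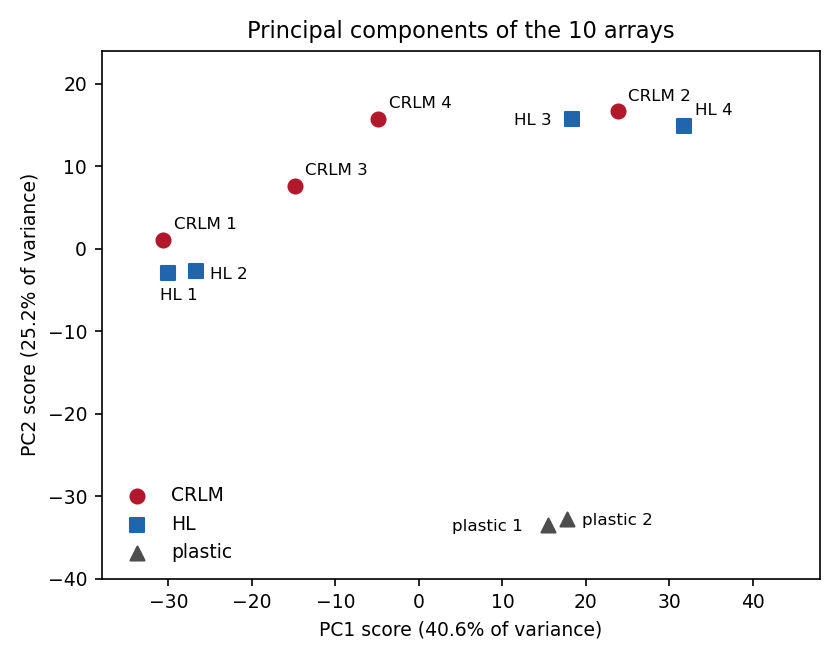
Scores of the 10 arrays on the first component (40.6% of variance) and the second (25.2%), with each point labelled by group and replicate. The plastic arrays lie near -33 on the second component, and CRLM and HL arrays mix along the first.

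The first comparison asked what growth in metastasis matrix changed in HT29 cells relative to flat culture. Cells in CRLM matrix expressed more of the genes induced by low oxygen and less of the DNA replication machinery. COXFA4L2 (also NDUFA4L2), a hypoxia-induced mitochondrial protein, rose 12.2-fold (log2 3.61 ± 0.20 SE, adjusted p = 5.13e-06, n = 4 and 2), and SLC11A2, which imports iron into enterocytes, rose 11.7-fold (3.55 ± 0.23). NDRG1, a hypoxia-responsive gene, rose 8.88-fold (3.15 ± 0.30), and TXNIP, which binds thioredoxin and restrains glucose uptake, rose 8.35-fold (3.06 ± 0.20). FAM111B, a protease expressed in S phase, fell 5.56-fold (log2 -2.47 ± 0.36) and MCM6, a subunit of the replicative helicase, fell 4.22-fold (-2.08 ± 0.20, adjusted p = 0.000131).

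In all, 912 genes passed the limma test in CRLM against plastic, 531 higher and 381 lower, of which 331 changed at least 2-fold. The other large rises were in ACSS2, which makes acetyl-CoA from acetate (7.74-fold), P4HA1, a collagen prolyl hydroxylase (6.23-fold), the transcriptional repressor BHLHE40 (6.14-fold), the immune checkpoint ligand HHLA2 (5.87-fold), the arrestin-domain gene ARRDC3 (5.83-fold) and the mitochondrial carrier SLC25A27 (5.63-fold). Beside FAM111B and MCM6, the largest falls were in cyclin CCNE2 (4.21-fold), DTL, which directs degradation of the licensing factor CDT1 (4.00-fold), the recombination gene XRCC2 (3.96-fold), annexin ANXA1 (3.81-fold), the protease CTSE (3.73-fold), the licensing factor CDC6 (3.72-fold), the actin-binding COTL1 (3.72-fold) and WDR76 (3.70-fold). Across all genes, 30.8% had the same sign in each CRLM array against both plastic arrays, where chance gives 13.3%. Leaving out plastic 1 gave 165 genes and leaving out plastic 2 gave 156, with 533 without CRLM 3 and 490 without CRLM 4. HHLA2 lost its call without plastic 1 (log2 2.35), and SLC25A27 (2.16) and FAM111B (-2.30) lost theirs without plastic 2. Leaving out the 3 arrays with the smallest SD (CRLM 2, HL 3 and HL 4) gave 2698 genes. With the SD of the array as a covariate most of the 2650 genes were lower, 1383 against 1267 higher.

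DEGs higher in CRLM matrix included 17 of 23 measured hypoxia-response genes, with none lower and 6 not past the threshold (18 higher adjusted over the list alone). EGLN3, an oxygen-sensing prolyl hydroxylase, rose 5.24-fold (2.39 ± 0.18), and the collagen-modifying enzymes P4HA2 and PLOD2 rose 4.09-fold and 4.11-fold. The list's median log2 change was 1.38 (camera adjusted p = 4.48e-25), and the call held with an estimated correlation (adjusted p = 0.0143). Of 18 glycolysis genes, 5 rose and none fell (7 and none adjusted over the list alone), among them ALDOC (3.47-fold), the regulator PFKFB3 (3.16-fold), PGK1 (2.07-fold) and LDHA (1.79-fold). The glycolysis median was 0.61 (camera adjusted p = 4.34e-06, adjusted p = 0.228 with an estimated correlation). Among 44 nuclear genes of oxidative phosphorylation, NDUFC1 (log2 -0.72 ± 0.15) and CYC1 (-0.62 ± 0.14) fell, none rose and 42 did not pass (2 fell adjusted over the list alone). That list's median was -0.21 (camera adjusted p = 0.000223, adjusted p = 0.457 with an estimated correlation).

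Of 29 DNA replication genes 23 fell, none rose and 6 did not pass (27 lower adjusted over the list alone), with CDC6, MCM6, the helicase cofactor GINS2 (3.62-fold) and the flap endonuclease FEN1 (3.51-fold) as examples. Their median was -1.29 (camera adjusted p = 7.79e-35), a call that held with an estimated correlation (adjusted p = 0.0199). Mitotic genes had 7 of 24 lower and none higher (18 lower adjusted over the list alone), including the proliferation marker MKI67 (log2 -0.99 ± 0.18), CDK1 (-0.91 ± 0.21), CCNB2 (-0.71 ± 0.15) and CDC20 (-0.63 ± 0.16). The mitotic median was -0.60 (camera adjusted p = 2.16e-12, adjusted p = 0.228 with an estimated correlation). Histones whose synthesis follows replication did not pass as a list (median -0.08, adjusted p = 0.635, and 0.910 with an estimated correlation), although H1-5 and H2BC14 fell and H2AC6 rose among 36.

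Cholesterol synthesis rose in 7 of 20 genes and fell in none (10 and none adjusted over the list alone), led by MSMO1 (3.44-fold), HMGCS1, the enzyme that makes HMG-CoA (2.81-fold), IDI1 (2.35-fold) and the sterol sensor partner INSIG1 (2.23-fold). The median was 0.51 (camera adjusted p = 3.08e-09, adjusted p = 0.228 with an estimated correlation). Metallothioneins, which bind zinc and copper, fell in 5 of 10 genes and rose in none (8 lower adjusted over the list alone), with MT1E at -1.18 ± 0.14 and MT2A at -1.18 ± 0.29. Their median was -0.65 (camera adjusted p = 3.06e-07, adjusted p = 0.228 with an estimated correlation). Interferon-stimulated genes rose in 4 of 35 and fell in none (7 adjusted over the list alone), namely GBP2 (1.96-fold), MX1 (2.40-fold), IFI27 (2.54-fold) and IFI6 (3.11-fold). The list's median was 0.51 (camera adjusted p = 7.14e-09, adjusted p = 0.233 with an estimated correlation). Antigen presentation rose in 3 of 17 genes and fell in none (5 adjusted over the list alone), namely the immunoproteasome subunit PSMB9 (2.07-fold) and the class I molecules HLA-E (2.04-fold) and HLA-C (1.83-fold). The median of 0.32 held at both settings (camera adjusted p = 0.000159, and adjusted p = 0.0354 with an estimated correlation).

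Epithelial junction genes rose in 5 of 26 and fell in 1 (9 and 1 adjusted over the list alone). Intestinal cadherin CDH17 (2.53-fold) and the desmosomal DSC2 (2.00-fold) and DSP (1.88-fold) rose, while the claudin CLDN1 fell (log2 -1.32 ± 0.17). The median was 0.24 (camera adjusted p = 0.000957, adjusted p = 0.233 with an estimated correlation). Among 25 goblet-cell genes the mucin MUC2 (2.63-fold) and the trefoil factor TFF3 (1.97-fold) rose and none fell (3 and none adjusted over the list alone). That median was 0.24 (camera adjusted p = 0.00559, adjusted p = 0.272 with an estimated correlation). Immediate early genes rose in 3 of 24 and fell in none (8 and 1 adjusted over the list alone), with JUNB at 2.11-fold, ATF3 at 2.21-fold and DUSP1 at 1.95-fold. Their median was 0.49 (camera adjusted p = 0.000482, adjusted p = 0.519 with an estimated correlation). Ribosomal protein genes had a median of 0.17 (camera adjusted p = 0.000817, adjusted p = 0.437 with an estimated correlation) with none of 40 past the threshold by limma.

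Of 20 integrin and laminin genes, the collagen receptor DDR1 (1.66-fold), the integrin ITGB4 (1.72-fold) and the syndecan SDC4 (1.67-fold) rose and none fell (5 and none adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.0362, adjusted p = 0.373 with an estimated correlation), and the call was lost without CRLM 1 (median 0.05) or plastic 2 (0.04), with the SD of the array as a covariate (0.05), with quantile normalization (0.17) and with dim probe sets filtered (0.23). Genes of the amino acid response fell in 7 of 26 and rose in 2 (9 and 3 adjusted over the list alone). The serine synthesis enzymes PSAT1 (log2 -1.52 ± 0.20) and PHGDH (-1.27 ± 0.20) fell with the transporters SLC7A5 (-1.37 ± 0.22) and SLC7A11 (-1.14 ± 0.20). The median was -0.17 (camera adjusted p = 0.0481, adjusted p = 0.730 with an estimated correlation), and the call was lost without CRLM 1 (median -0.02), CRLM 2 (-0.20), HL 3 or HL 4 (-0.17 each) or plastic 1 (-0.19), without CRLM 2, HL 3 and HL 4 together (-0.20), with quantile normalization (-0.14) and with the SD of the array as a covariate (-0.11). Enterocyte genes did not pass as a list (median 0.06, adjusted p = 0.0740, and 0.228 with an estimated correlation), with 4 of 30 higher and 1 lower (7 and 2 adjusted over the list alone). CEACAM7 (4.67-fold), the fatty acid carrier FABP1 (2.61-fold) and the intestinal regulator CDX2 (1.77-fold) rose and carbonic anhydrase CA2 fell (log2 -0.91 ± 0.18).

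**Figure D2:**
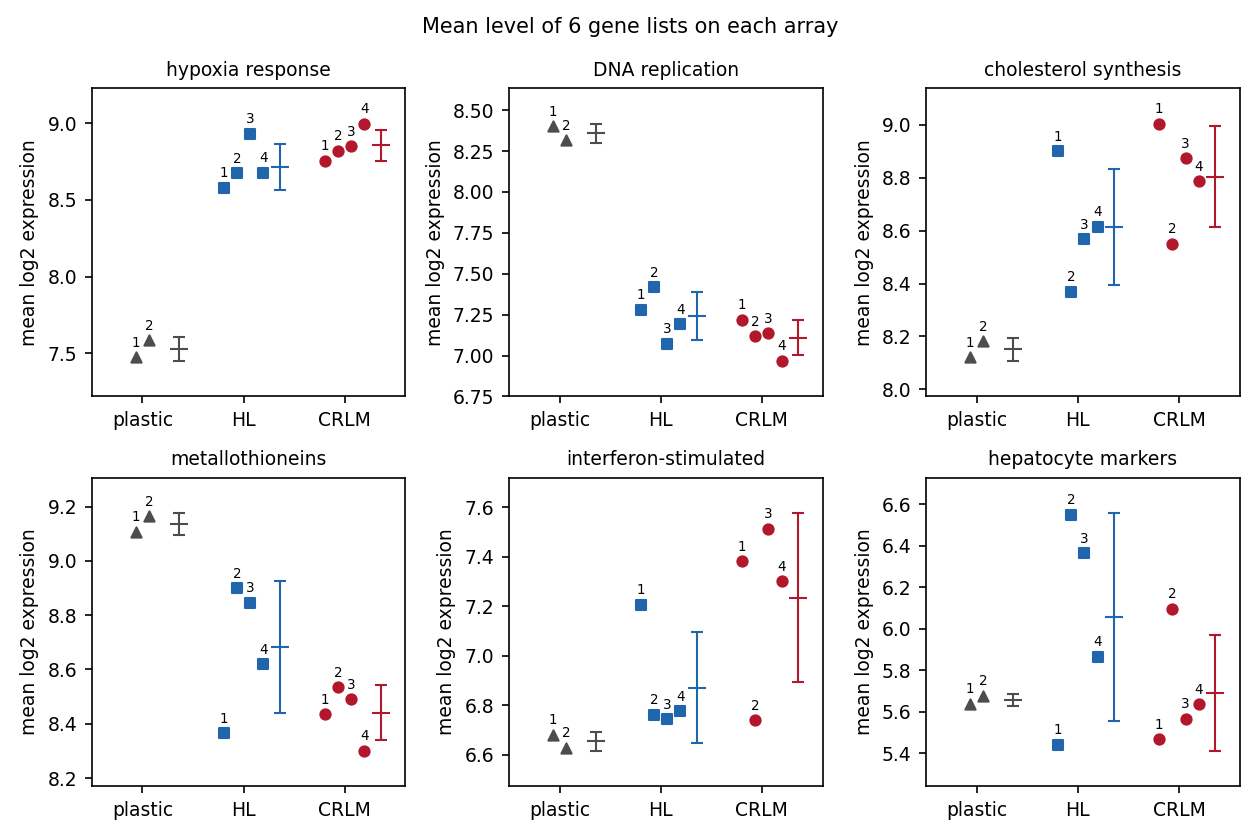
Mean log2 expression of the measured genes of 6 lists on each array (points, numbered by replicate) with the group mean and SD (bars beside the points) for plastic, HL and CRLM. Hypoxia-response genes lie higher and DNA replication genes lower on each matrix array than on both plastic arrays, while interferon-stimulated genes and hepatocyte markers overlap between the matrices.

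The second comparison put healthy liver matrix against flat culture. SLC11A2 rose 10.0-fold in HL (log2 3.32 ± 0.23, adjusted p = 2.14e-05, n = 4 and 2), COXFA4L2 9.39-fold (3.23 ± 0.20), TXNIP 8.84-fold (3.14 ± 0.20) and NDRG1 7.24-fold (2.86 ± 0.30). HES1, a repressor downstream of Notch, fell 3.92-fold (log2 -1.97 ± 0.22) and MCM6 fell 3.91-fold (-1.97 ± 0.20, adjusted p = 0.000356). Further rises were in P4HA1 (5.95-fold), SLC25A27 (5.23-fold), ACSS2 (5.17-fold), HHLA2 (5.06-fold), ARRDC3 (5.03-fold) and EGLN3 (4.71-fold). Further falls were in FAM111B (3.83-fold), the calcium-binding CALB2 (3.70-fold), CCNE2 (3.67-fold), ANXA1 (3.50-fold), CTSE (3.50-fold), DTL (3.43-fold), the collagen-modifying P3H2 (3.38-fold) and MCM3 (3.32-fold).

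In HL against plastic 540 genes passed, 279 higher and 261 lower, of which 219 changed at least 2-fold. The same sign in each HL array against both plastic arrays was seen for 24.8% of all genes, where chance gives 13.3%. The count was 62 without plastic 1, 80 without plastic 2 and 334 without HL 3, and 2388 without CRLM 2, HL 3 and HL 4. The majority of higher genes turned to one of lower genes without HL 1 (190 higher, 204 lower), HL 2 (179 and 209) or CRLM 4 (206 and 207), and with the SD of the array as a covariate (1008 and 1083). SLC25A27 (log2 2.72 and 2.06), ACSS2 (2.38 and 2.37), HHLA2 (2.13 and 2.55), FAM111B (-2.11 and -1.76) and DTL (-1.79 and -1.77) lost their calls without plastic 1 or plastic 2. CCNE2 (-1.82) and CTSE (-1.53) lost theirs without plastic 1. P3H2 lost its call without either plastic array (-1.75 and -1.77), HL 2 (-1.80), HL 3 (-1.52) or HL 4 (-1.66) and after quantile normalization (-1.73).

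Hypoxia-response genes rose in 13 of 23 and fell in none (18 higher adjusted over the list alone), with P4HA2 at 3.84-fold and PLOD2 at 3.95-fold. Their median was 1.22 (camera adjusted p = 2.48e-26, and adjusted p = 0.0123 with an estimated correlation). DNA replication fell in 23 of 29 genes and rose in none (26 lower adjusted over the list alone), with CDC6 at 3.11-fold and GINS2 at 3.08-fold. That median was -1.08 (camera adjusted p = 2.74e-36, and adjusted p = 0.0177 with an estimated correlation). Mitotic genes had 2 of 24 lower, CCNB2 (log2 -0.62 ± 0.15) and AURKB (-0.70 ± 0.17), and none higher (17 lower adjusted over the list alone). Their median was -0.51 (camera adjusted p = 1.99e-11, adjusted p = 0.363 with an estimated correlation). Glycolysis rose in 4 of 18 genes and fell in none (5 and none adjusted over the list alone), namely LDHA (1.81-fold), PGK1 (2.06-fold), ALDOC (2.75-fold) and PFKFB3 (2.16-fold). The glycolysis median was 0.38 (camera adjusted p = 3.62e-05, adjusted p = 0.376 with an estimated correlation). NDUFC1 (log2 -0.70 ± 0.15) and CYC1 (-0.65 ± 0.14) fell among 44 oxidative phosphorylation genes (6 lower adjusted over the list alone). The median there was -0.20 (camera adjusted p = 3.45e-05, adjusted p = 0.387 with an estimated correlation), and -0.13 with no call without CRLM 2, HL 3 and HL 4.

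Cholesterol synthesis had a median of 0.31 in HL (camera adjusted p = 2.42e-06, adjusted p = 0.376 with an estimated correlation), and MSMO1 rose 2.86-fold as the single gene of 20 past the threshold (6 higher adjusted over the list alone). Metallothioneins had a median of -0.45 (camera adjusted p = 0.000158, adjusted p = 0.376 with an estimated correlation), with MT1E lower (log2 -1.04 ± 0.14) as 1 of 10 (5 lower adjusted over the list alone). The amino acid response had 5 of 26 genes lower and none higher (9 and 2 adjusted over the list alone), including SLC7A5 (log2 -1.53 ± 0.22), PSAT1 (-1.40 ± 0.20) and PHGDH (-1.33 ± 0.20). Its median was -0.22 (camera adjusted p = 0.00241, adjusted p = 0.457 with an estimated correlation). Ribosomal protein genes had a median of 0.17 (camera adjusted p = 0.000115, adjusted p = 0.387 with an estimated correlation) with none of 40 past the threshold by limma.

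Junction genes rose in 5 of 26 and fell in 1 in HL (7 and 1 adjusted over the list alone), with DSP (1.77-fold), DSC2 (1.86-fold) and CDH17 (1.99-fold) higher and CLDN1 lower (log2 -1.40 ± 0.17). The median was 0.19 (camera adjusted p = 0.00513, adjusted p = 0.376 with an estimated correlation). Enterocyte genes had CEACAM7 (4.58-fold) and FABP1 (2.58-fold) higher and CA2 lower among 30 (6 and 1 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.00876, adjusted p = 0.111 with an estimated correlation), with 0.02 and no call once CRLM 2, HL 3 and HL 4 were left out. Antigen presentation rose in 2 of 17 genes, PSMB9 (1.84-fold) and HLA-E (1.77-fold), and fell in none (2 adjusted over the list alone). Its median was 0.15 (camera adjusted p = 0.00618, adjusted p = 0.111 with an estimated correlation), with 0.11 and no call without CRLM 2, HL 3 and HL 4. TFF3 (1.74-fold) rose as 1 of 25 goblet-cell genes (1 adjusted over the list alone), whose median was 0.14 (camera adjusted p = 0.0331, adjusted p = 0.387 with an estimated correlation). The goblet-cell call was lost without HL 4 (median 0.14) or plastic 1 (0.16), without CRLM 2, HL 3 and HL 4 together (0.02) and with dim probe sets filtered (0.19).

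Interferon-stimulated genes had a median of 0.21 in HL against plastic (camera adjusted p = 0.00886, adjusted p = 0.553 with an estimated correlation). GBP2 rose (1.88-fold) as the single gene of 35 past the threshold, and the call was lost without HL 1 (median 0.08). NF-kB targets and chemokines had a median of 0.09 (camera adjusted p = 0.0482, adjusted p = 0.533 with an estimated correlation), and the inhibitor TNFAIP3 rose 3.32-fold as 1 of 22. Leaving out CRLM 1 or CRLM 2 (median 0.09 each), HL 2 (0.10), HL 3 (0.07), HL 4 (0.05), plastic 1 (0.17) or plastic 2 (0.11) ended that call, as did quantile normalization (0.09), and the median was -0.06 without CRLM 2, HL 3 and HL 4. Hepatocyte markers had a median of 0.30 (camera adjusted p = 0.0125, adjusted p = 0.533 with an estimated correlation) with none of 25 past the threshold by limma and 19 above 0. Their mean on the HL arrays ran from 5.44 on HL 1 to 6.55 on HL 2, against 5.64 and 5.68 on plastic, and the call was lost without HL 3 (median 0.145) or plastic 1 (0.13), without CRLM 2, HL 3 and HL 4 together (0.09), and with dim probe sets filtered (0.02, adjusted p = 0.322).

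Fold changes against plastic were compared between the matrices to see what both cultures shared. TXNIP, NDRG1, SLC11A2 and P4HA1 were among 269 genes called higher in both comparisons, and MCM6, DTL, CCNE2 and ANXA1 among 242 called lower in both, with 0 called in opposite directions. Independent calls would have overlapped in 8.38 and 5.62 genes. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.924 with a covariance of 0.117, and 84.5% of genes had the same sign. Both comparisons used the same plastic arrays, and unchanged groups simulated against shared controls gave r = 0.666, a covariance of 0.0303, 73.2% of genes with the same sign and 0.02 genes called in both on average over 100 draws. The covariance exceeded the simulated value by 0.0864. The simulated noise was independent between genes, unlike variation shared across genes on the real arrays. Unchanged groups of real arrays could therefore give other values. The 2 plastic arrays cannot be split into sets of at least 2, so part of the excess may come from the shared controls. Taking both matrices together against plastic, 1046 genes passed, 582 higher and 464 lower, with 168 after leaving out either plastic array and 3537 without CRLM 2, HL 3 and HL 4. With the SD of the array as a covariate 1370 were higher and 1524 lower.

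**Figure D3:**
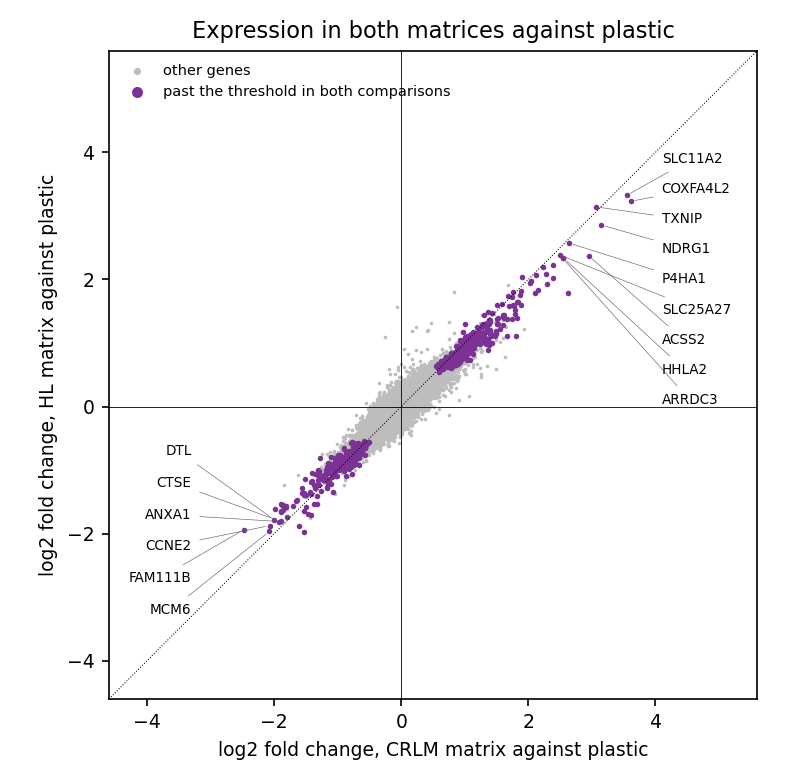
Log2 fold change of each gene in CRLM matrix (horizontal) and in HL matrix (vertical) against plastic, with genes past the threshold in both comparisons in purple, all on the same side of 0, and the dotted line marking equal change. Named genes include COXFA4L2, SLC11A2 and TXNIP at the upper end and MCM6 and FAM111B at the lower end.

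The comparison for which the series is titled put metastasis matrix against healthy liver matrix. No single gene passed limma (0 of 17680), and 269 genes had an unadjusted p under 0.05 where chance gives 884. That count was 962 with the SD of the array as a covariate and 1152 without CRLM 2, HL 3 and HL 4. Both settings were added after the data had been seen. The low count therefore does not show that the matrices act alike. The genes with the smallest p among those of one sign in all 4 donor pairs were, on the higher side, the pyrimidine salvage enzyme CDA (log2 0.70 ± 0.18 SE, n = 4 and 4), RAB30 (0.80 ± 0.22), KL (0.50 ± 0.15), ARFGEF3 (0.43 ± 0.13) and ZNF20 (0.40 ± 0.12). On the lower side they were SMLR1 (-0.72 ± 0.20), the thioesterase ACOT4 (-0.60 ± 0.17), REEP1 (-0.51 ± 0.13), N4BP2L1 (-0.49 ± 0.14) and the kinetochore scaffold KNL1 (-0.46 ± 0.14). Each had an adjusted p of 1. All of these genes but ARFGEF3 (mean 7.9 in CRLM and 7.5 in HL) had means under 6.88, the level of the dim filter, in both matrices. REEP1 was the lowest (3.30 in CRLM and 3.81 in HL). One sign in all 4 donor pairs was seen for 689 genes higher and 509 lower in CRLM, 6.78% of the total, where chance gives 12.5%. The median half-width of a gene's unadjusted 95% interval was 0.34. With donor as a fixed block in the 8 matrix arrays, the count past the threshold was again 0, with 200 genes at an unadjusted p under 0.05.

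Gene lists gave small differences between the matrices, in which no single member passed. They were called with a preset correlation between genes but not with an estimated one. Camera at a preset correlation called 14 of 36 lists, 9 toward CRLM and 5 toward HL. With an estimated correlation it called 0, where the smallest adjusted p was 0.175. For antigen presentation the estimate was -0.0105, below the preset 0.01, yet the unadjusted camera p rose from 0.000168 to 0.00485. The loss of that call thus did not come from a higher correlation between genes. Exact permutation of the matrix labels on the mean list score gave its smallest two-sided p, 0.0286, for antigen presentation, and the adjusted value was 0.808 for that list and no lower for any other of the 36. The value 0.0286 is the smallest that the design allows, so over 36 lists it can pass adjustment only if many lists reach it. The adjusted value of 0.808 therefore does not argue against a difference in antigen presentation. Leaving out CRLM 2 gave 24 lists.

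Toward CRLM, interferon-stimulated genes had a median log2 difference of 0.31, with 32 of 35 above 0 (camera adjusted p = 7.77e-16, adjusted p = 0.289 with an estimated correlation). OAS2 (0.89 ± 0.29), IFI6 (0.86 ± 0.33), MX1 (0.75 ± 0.25) and IFI27 (0.71 ± 0.27) were the members with the smallest p. Their mean level was 7.23 ± 0.34 (SD) in CRLM and 6.87 ± 0.22 in HL, and it was higher in CRLM in 3 of 4 donor pairs. Antigen presentation had a median of 0.10 (camera adjusted p = 0.000866, adjusted p = 0.175 with an estimated correlation) and a higher mean level in 4 of 4 pairs, with the peptide transporter TAP1 at 0.42 ± 0.16 and HLA-C at 0.40 ± 0.15. All 24 immediate early genes lay above 0, with a median of 0.21 (camera adjusted p = 1.01e-12, adjusted p = 0.382 with an estimated correlation) and KLF4 (0.53 ± 0.16), JUND (0.44 ± 0.17) and JUNB (0.34 ± 0.14) as examples, and their mean level was higher in CRLM in 3 of 4 pairs and lower in donor 2 (-0.25). Cholesterol synthesis had a median of 0.22 and 17 of 20 genes above 0 (camera adjusted p = 1.59e-05, adjusted p = 0.382 with an estimated correlation), with INSIG1 at 0.37 ± 0.20 and FDPS at 0.41 ± 0.23, and a higher mean level in 4 of 4 pairs.

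Toward HL, all 10 metallothioneins lay below 0, with a median of -0.23 (camera adjusted p = 1.10e-06, adjusted p = 0.382 with an estimated correlation), MT2A at -0.44 ± 0.23 and MT1B at -0.38 ± 0.17. Their mean level was lower in CRLM in 3 of 4 pairs and higher in donor 1 (0.07), and so was that of hepatocyte markers (0.03 in donor 1). From HL 1 to HL 4 the mean levels were 8.37, 8.90, 8.85 and 8.62 for metallothioneins and 5.44, 6.55, 6.37 and 5.87 for hepatocyte markers, and CRLM 2 had the highest CRLM level of both lists (8.54 and 6.10). On the 2 plastic arrays metallothioneins were higher (9.11 and 9.16) with hepatocyte markers at 5.64 and 5.68. DNA replication genes had a median of -0.12 with 24 of 29 below 0 (camera adjusted p = 1.59e-05, adjusted p = 0.382 with an estimated correlation), MCM4 at -0.37 ± 0.14 among them, and the call was lost without HL 2 (median -0.07). Their mean level was lower in CRLM in 3 of 4 pairs and higher in donor 3 (0.07). Hepatocyte markers had a median of -0.18 with 21 of 25 below 0 (camera adjusted p = 2.09e-05, adjusted p = 0.413 with an estimated correlation). Of these, albumin (ALB) lay at -1.02 ± 0.51, transferrin (TF) at -0.86 ± 0.46 and APOA2 at -1.63 ± 0.96, and on HL 2 the level of APOA2 was 8.95 against 4.22 on average on the other 9 arrays. Metallothioneins, hepatocyte markers and the 4 lists toward CRLM named above kept their calls whichever 1 of the 10 arrays was left out.

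The other 7 calls between the matrices were lost when single arrays were left out. Hypoxia-response genes had a median of 0.09 (camera adjusted p = 0.00435, adjusted p = 0.382 with an estimated correlation), with BHLHE40 at 0.83 ± 0.28 and adrenomedullin (ADM) at 0.70 ± 0.27, and no call without HL 1 (0.06) or HL 4 (0.07). Glycolysis had a median of 0.05 (camera adjusted p = 0.0302, adjusted p = 0.526 with an estimated correlation), PFKFB3 at 0.55 ± 0.22, and no call without HL 1, where the median turned to -0.01, HL 2 (0.01), CRLM 3 (0.02), CRLM 4 (0.07) or HL 4 (0.10), with quantile normalization or with dim probe sets filtered (0.05 each). Fatty acid synthesis had a median of 0.20 (camera adjusted p = 0.0248, adjusted p = 0.382 with an estimated correlation), SREBF1 at 0.41 ± 0.20, and no call without CRLM 1 (0.20), HL 2 (0.18), CRLM 3 (0.23), HL 3 (0.15), CRLM 4 (0.25) or HL 4 (0.21), without CRLM 2, HL 3 and HL 4 together (0.28) or with the SD of the array as a covariate (0.24). YAP and TGF-beta targets had a median of 0.08 (camera adjusted p = 0.0160, adjusted p = 0.289 with an estimated correlation), ID3 at 0.33 ± 0.12, and no call without HL 3 (0.08), CRLM 4 (0.06) or HL 4 (0.10), or without CRLM 2, HL 3 and HL 4 together (0.07). Goblet-cell genes had a median of 0.11 (camera adjusted p = 0.0472, adjusted p = 0.482 with an estimated correlation), MUC13 at 0.37 ± 0.20, and no call without CRLM 1 (0.09), HL 1 (0.11), HL 2 (0.06), CRLM 3 (0.13), HL 3 (0.08), CRLM 4 (0.05) or either plastic array (0.11), with quantile normalization (0.10), median centring (0.11) or the SD of the array as a covariate (0.11). Mitotic genes had a median of -0.12 (camera adjusted p = 0.0160, adjusted p = 0.658 with an estimated correlation), MKI67 at -0.27 ± 0.15, and no call without CRLM 1 (-0.09), HL 1 (-0.07), CRLM 2 (-0.09), HL 2 (-0.07), HL 3 (-0.06) or CRLM 4 (-0.03). NF-kB targets and chemokines had a median of -0.07 (camera adjusted p = 0.0236, adjusted p = 0.482 with an estimated correlation), CCL20 at -0.98 ± 0.46, and no call without CRLM 1 (-0.02), HL 2 (-0.10), CRLM 3 (-0.02) or HL 4 (-0.05), without CRLM 2, HL 3 and HL 4 together (-0.05), with dim probe sets filtered (-0.03) or with the SD of the array as a covariate (-0.06).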

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

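The 3 tests of the liver transcripts on HL 2 and the test of matrix type on the first component were chosen after the results had been seen, and the array SD as a covariate was added after the data had been seen.

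Liver transcripts were high on HL 2, where 12 of 20 secreted liver proteins exceeded the other 9 arrays, with APOA2 at 8.95 against a mean of 4.22 on those arrays, AHSG at 9.48 against 4.86 and APOB at 8.07 against 3.62, and where CRLM 2 of the same donor had the highest class mean among the CRLM arrays (6.52, the others 5.71 to 5.85, HL 3 at 6.62). For HL 2, the mature hepatocyte class showed little sign of RNA of mature hepatocytes left in the matrix. Of its 19 genes 1 exceeded the other 9 arrays, with a median excess of -0.126. CYP2E1 was at 4.57 against 4.76 on the other arrays. The median excess of the secreted class exceeded that of the mature class by 1.56 log2 units (bootstrap SE 0.740). That SE resamples genes of this array, which are not independent replicates. The mature class held HP and HPX (excess -0.126 and -0.252), which are secreted too. The difference between the classes thus depends on how genes were assigned and does not settle the explanation. On HL 3 RNA of mature hepatocytes stays open as well, since 8 of 19 mature hepatocyte genes exceeded the other 9 arrays. The median excess was 0.385 there, against -0.126 on HL 2, with HP at 6.51 and ALB at 8.01 on HL 3. However, HL 3 is also among the arrays with a small SD. A response of HT29 to HL matrix as such is argued against by the mean of secreted liver proteins. On 2 of 4 HL arrays it lay at or below the highest plastic or CRLM array. Of these, HL 4 (6.07) lay below CRLM 2 only, and HL 1 (5.73) lay below both plastic arrays (5.88 and 5.94). Without CRLM 2 as the bar, the argument rests on HL 1. RNA of fetal-type or hepatoma-type liver cells is a candidate explanation, since 4 of 7 measured genes of that class exceeded the other 9 arrays, with AFP at 7.25 against a mean of 4.09, GPC3 at 8.65 against 5.46, IGF2 at 9.98 against 8.96 and PEG10 at 5.42 against 4.68, and CRLM 2, an array with a small SD, came next for AFP (5.04), GPC3 (6.12) and PEG10 (5.03) but not for IGF2, although 2 of the 7 also lay above the median of all values on both plastic arrays and the labels name no such cells and no sort, and a source shared by the cultures of donor 2 and a change in the HT29 cells both stay open.

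The 8 matrix arrays spread along a first component with 55.9% of their variance, whose score followed the SD of the array (Pearson r = -0.993, exact permutation p = 4.96e-05, Spearman rho = -0.976, exact permutation p = 0.000397, n = 8, and r = -0.985 without the 2 arrays farthest from the median). A single monotone distortion of the scale per array is argued against, since quantile normalization left 53.3% on that component. Matrix type is argued against, since 4 of 4 CRLM arrays scored within the range of the HL arrays. Bias with the span of the gene may be part of it, since loadings correlated with gene span at a median of -0.26 across genes, which are not independent replicates, within 10 classes of mean level. The quality of the RNA stays open, as do differences between the cultures other than matrix type, which were not tested.

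Interferon-stimulated genes had a median log2 difference of 0.310 between CRLM and HL, with HL 1 at 7.21 where the other HL arrays lay between 6.74 and 6.78, and CRLM 2 at 6.74 where the other CRLM arrays lay between 7.30 and 7.51. The spread of values of the array as the whole cause is argued against, since the median was 0.246 with the array SD as a covariate. A single array as the cause is argued against, since the median was 0.220 or higher whichever of the 8 matrix arrays was left out, and 0.528 without CRLM 2. A difference between the matrices in list score and chance cannot be told apart, with a two-sided exact permutation p of 0.143, or 0.250 within donor pairs, where 4 pairs allow no p under 0.125. A biological difference between the matrices may thus be present and stays open.

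For the count of genes in CRLM against HL the splits of the 8 matrix arrays say nothing about chance, since the real count is 0 and 35 of 35 splits give as many by construction, with 5634 in the highest other split. Some genes passed in 3 splits. The split with 5634 genes set CRLM 1, HL 1, HL 2 and CRLM 3 against the other matrix arrays. These arrays scored -10.5 or lower on the first component of the matrix arrays, and the others 1.30 or higher. That split thus followed the first component and not matrix type. Chance cannot be excluded for the 14 lists, since 6 of 35 splits, the real one included, gave as many and the highest other split gave 18. The splits that part all 4 donor pairs number 8 with the real one, too few for a share under 0.05, and the highest of the others gave 0 genes and 15 lists.

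Of 112 groups of 4 arrays tested for a single array far from the rest, 5 had one, and chance gives 5.6. CCNE2 was at 5.61 on HL 2 and between 4.70 and 4.76 on the other HL arrays. The mean of fatty acid synthesis genes was 8.10 on CRLM 2 and 8.43 to 8.46 on the other CRLM arrays. Immediate early genes averaged 8.66 on HL 3 and 8.95 to 9.01 on the other HL arrays. Amino acid response genes averaged 8.28 on HL 3 and 8.04 to 8.06 on the other HL arrays. Interferon-stimulated genes on HL 1 were the fifth case.

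The difference between the responses of CRLM and HL cultures relative to plastic equals CRLM against HL, since plastic cancels. It is the same comparison as above, with 14 lists called by camera at a preset correlation and none with an estimated one. The median log2 differences toward CRLM were 0.310 for interferon-stimulated genes, 0.217 for cholesterol synthesis, 0.214 for immediate early genes, 0.198 for fatty acid synthesis, 0.109 for goblet-cell genes, 0.102 for antigen presentation, 0.0922 for the hypoxia response, 0.0760 for YAP and TGF-beta targets and 0.0478 for glycolysis. Toward HL they were -0.228 for metallothioneins, -0.181 for hepatocyte markers, -0.124 for DNA replication, -0.118 for mitotic genes and -0.0722 for NF-kB targets and chemokines.

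Among 3137 probe sets without a gene symbol, which the comparisons above left out, 69 were higher and 20 lower in CRLM than on plastic. In HL 40 of them were higher and 12 lower than on plastic.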

How the results depend on the processing

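The array SD as a covariate and the fit without CRLM 2, HL 3 and HL 4 were chosen after seeing the data. CRLM against HL gave 0 genes by limma under every alternative, with 200 at an unadjusted p under 0.05 with donor as a fixed replicate block, 739 with array weights and 1152 without the 3 arrays. No described gene or called list changed the direction of its call under any alternative run, though the medians of 2 lists changed sign where the call was lost (glycolysis in CRLM against HL at -0.01 without HL 1, NF-kB targets in HL against plastic at -0.06 without the 3 arrays). Counts below are for CRLM against plastic, HL against plastic and both matrices against plastic in this order. They rose to 2851, 2052 and 3424 with array weights, 2650, 2091 and 2894 with the array SD as a covariate, where 47.8%, 48.2% and 47.3% were higher in place of 58.2%, 51.7% and 55.6%, and 2698, 2388 and 3537 without the 3 arrays, and the cause was not tested. They fell to 331, 219 and 295 at 2-fold or more and to 302, 174 and 350 at an adjusted p under 0.01, as stricter rules must. With 1 array left out they ran from 156 to 1070, from 62 to 633 and from 168 to 1240, lowest without plastic 2, plastic 1 and either plastic array, where fewer controls remain and the lone plastic array is assumed to vary like the other groups. Quantile normalization, median centring, the filter on dim probe sets and eBayes with trend and robust kept every count within 1.5 times, and donor as a random replicate block gave 912, 540 and 1047. Lists called in CRLM against HL numbered 10 to 24 with 1 array left out (24 without CRLM 2) and 16 with donor as a fixed block, which ended no call. With an estimated correlation 0 lists were called in CRLM against HL, 3 in CRLM against plastic and 2 in HL against plastic. The shared response to both matrices, as a correlation across genes, was 0.958 with dim probe sets filtered and 0.873 to 0.933 with 1 array left out. Of the genes named against plastic, 17 of 20 in CRLM and 12 of 20 in HL passed whichever array was left out, as did 6 of 14, 13 of 16 and 12 of 17 lists in CRLM against HL, CRLM against plastic and HL against plastic. Under at least 1 of the other alternatives 5, 3 and 7 lists lost their call in these comparisons. In CRLM against HL they were glycolysis (quantile, dim filter), goblet-cell genes (quantile, centring, array SD), NF-kB targets (dim filter, array SD, 3 arrays), fatty acid synthesis (array SD, 3 arrays) and YAP targets (3 arrays). In CRLM against plastic they were amino acid response (quantile, array SD, 3 arrays), integrins (quantile, dim filter, array SD) and handling of fluoropyrimidine and irinotecan (3 arrays). In HL against plastic they were handling of fluoropyrimidine and irinotecan (quantile, centring, 3 arrays), NF-kB targets (quantile, 3 arrays), goblet-cell genes and hepatocyte markers (dim filter, 3 arrays), and oxidative phosphorylation, antigen presentation and enterocyte genes (3 arrays). No detection calls were used, so dim probe sets near background are not separated from absent transcripts.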

Other observations

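All lists in this part were fixed beforehand. The fit without the arrays of smallest SD, used for the fluoropyrimidine and irinotecan genes, was added after the data had been seen. None of the other tests in this part was chosen after the result was seen. Several groups outside the main account held single genes that changed against plastic in both matrices. Among 20 p53 target genes, TP53INP1 rose 2.83-fold in CRLM and 3.03-fold in HL, and the cell cycle inhibitor CDKN1A rose 2.43-fold and 2.02-fold. GADD45A rose (1.61-fold) and BAX fell (log2 -0.57 ± 0.14) in CRLM, and as a list p53 targets did not pass in CRLM (median 0.06, camera adjusted p = 0.0854) or HL (0.05, adjusted p = 0.180). Of 23 intestinal stem and Wnt target genes, the Wnt inhibitor DKK1 (log2 -1.52 ± 0.18 in CRLM and -1.65 ± 0.18 in HL) and cyclin CCND1 (-0.79 ± 0.20 and -0.95 ± 0.20) fell in both, and AXIN2 rose 1.71-fold in CRLM. That list did not pass in CRLM (median -0.11, camera adjusted p = 0.189) or HL (-0.09, adjusted p = 0.108). Of 21 NRF2 and glutathione genes, NQO1 (log2 -1.05 ± 0.17 and -0.90 ± 0.17), the cystine transporter SLC7A11 and AKR1B10 fell in both, and GSR fell in CRLM, with list medians of -0.09 (camera adjusted p = 0.331) and -0.12 (0.314).

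Genes that handle fluoropyrimidines and irinotecan fell in 5 of 22 and rose in 1 in CRLM, and fell in 4 and rose in 1 in HL (5 and 2 adjusted over the list alone in each). Thymidine kinase TK1 (log2 -1.50 ± 0.17 and -1.39 ± 0.17) and the ribonucleotide reductase subunit RRM2 (-1.64 ± 0.20 and -1.47 ± 0.20) fell in both, and the cytochrome CYP3A5 rose 2.45-fold and 2.23-fold. The list medians were -0.25 in CRLM (camera adjusted p = 0.0152, adjusted p = 0.234 with an estimated correlation) and -0.17 in HL (camera adjusted p = 0.0482, adjusted p = 0.376 with an estimated correlation). The call in CRLM was lost without CRLM 2 (median -0.19) and without CRLM 2, HL 3 and HL 4 together (-0.19). That in HL was lost without CRLM 2 (-0.17), HL 3 (-0.11), HL 4 (-0.07), plastic 2 (-0.20) or the 3 arrays together (-0.08), with quantile normalization (-0.16) and with median centring (-0.17). RRM1, RRM2 and TYMS are also DNA replication genes.

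Invasion and mesenchymal genes did not pass as lists. The urokinase receptor PLAUR rose 2.28-fold in CRLM as 1 of 28 proteases and inhibitors, and lay at log2 0.67 ± 0.20 in HL, where it did not pass. SNAI1 (1.71-fold) and TGFB1 (1.60-fold) rose in CRLM among 22 mesenchymal genes, and 0 passed limma in HL. The adjusted camera p was 0.651 and 0.471 for the proteases and 0.547 and 0.232 for the mesenchymal genes in CRLM and HL. In CRLM both lists had a median below 0 (-0.01 and -0.04) and a mean above 0 (0.01 and 0.03). Of 21 YAP and TGF-beta targets, ID1 rose (1.81-fold and 1.59-fold) and CCN2 fell (log2 -0.89 ± 0.19 and -0.92 ± 0.19) in both matrices, with camera adjusted p of 0.890 and 0.383, and in CRLM the median was above 0 and the mean below it. The mitochondrial chaperonin HSPD1 fell in both (log2 -0.90 ± 0.14 and -0.67 ± 0.14) as the single heat shock gene of 12 past the threshold. Acetyl-CoA synthetase ACSS2 was the single gene of 11 in fatty acid synthesis past the threshold in both, with camera adjusted p of 0.217 and 0.632 and, in HL, a median below 0 (-0.06) and a mean above it (0.18). TNFAIP3 rose 3.33-fold in CRLM, where NF-kB targets did not pass as a list (median 0.03, camera adjusted p = 0.428). In the unfolded protein response HERPUD1 rose (1.73-fold) and SEC61B fell (log2 -0.72 ± 0.15) in CRLM, with a median of -0.04, a mean of 0.04 and a camera adjusted p of 0.460.

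Markers of other cell types of liver and blood gave no call against plastic in CRLM, with hepatocyte markers at a median of -0.04 and a mean of 0.03 (camera adjusted p = 0.592). Fibroblast and stellate (adjusted p = 0.512 in CRLM and 0.993 in HL), endothelial (0.404 and 0.633), macrophage and neutrophil (0.651 and 0.966), lymphocyte (0.254 and 0.369) and erythroid markers (0.912 and 0.894) did not pass in either. CD68, a lysosomal protein used as a macrophage marker, was the single marker past the threshold, at 2.23-fold in CRLM and 2.12-fold in HL.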
